A study of Mus musculus with 96 samples.

How the data were processed

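RNA sequencing counts were analysed for 96 libraries of mouse tissue, 48 of hypothalamus, 24 of sWAT and 24 of eWAT. Per the labels, RNA was extracted with a column kit from pooled tissue and sequenced on an Illumina instrument. Per the submitters' processing notes, the authors used Bowtie2 2.1.0, TopHat2 2.0.10, SAMtools 0.1.19, HTSeq 0.6.1p1, edgeR 3.12.0 and R 3.2.2 with the mouse build GRCm38; their order, settings, strand setting and annotation release are not given in the sources used here. The deposited values used here are whole-number counts per Ensembl gene, 1 table per library, with the counter's summary lines at the end. These lines were kept out of library sizes and tests. The no-feature line held 7.72% to 11.2% of the counted reads in the hypothalamus (median 10.2%), 3.72% to 6.59% in sWAT (median 4.61%) and 3.97% to 7.76% in eWAT (median 4.52%).

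The authors also deposited tables of 15371 genes for the hypothalamus and 18202 genes for both fat pads, which are named as CPM but hold whole-number counts equal to those of the single libraries. The 4 columns of D14071618 and D14071620 for the hypothalamus, 2 pools each, held each other's counts when set against the single tables. The single tables were used, and the exchanged naming was run as an alternative. All columns of both tables belong to the series' samples.

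Groups were taken from the labels: tissue, diet code and, for the hypothalamus, pool number. The labels describe the pools of a diet as made from different animals of 1 diet group. In the trends and series differences each diet was 1 sample, so p-values rest on the scatter of diets around a line within a series. In the test of any difference they rest on the spread between the pools of a diet. In the depot test they rest on how the depot difference varied between diets. Pool numbers did not pair the samples: over 276 pairs of diets, deviations of same-numbered pools correlated between -0.81 and 0.68 (median 0.05), with 101 pairs over 0.1. The labels do not say whether the sWAT and the eWAT pieces of a diet came from the same animals. No 2 libraries were identical, and the pools of a diet differed by more than sampling noise (lowest mean chi-square per gene 3.58).

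The test was edgeR 4.0.16's quasi-likelihood F test with TMM factors, on genes with at least 1 CPM in at least 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The counts of both hypothalamus pools of a diet were summed, which gave 24 samples per tissue. The model held a mean and a slope on the code position for each of the 4 series, with positions centred and scaled so that a slope is the fitted log2 change from the first to the last code. SE is the log2 change divided by the square root of F. The trend of a pair of series is the mean of 2 slopes, and the difference of 2 series is taken at the middle of the codes. The test of any difference used all 48 hypothalamus pools in 24 diet groups. The depot test used all 48 adipose libraries with the diet as a block. CPM values are counts scaled to the reads assigned to genes, with no offset unless a pseudocount of 1 is named.

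Gene lists were fixed before the data were examined, 60 in all, covering pathways, cell types and neighbouring tissues. Of these 33 were tested in the hypothalamus, 39 in sWAT, 40 in eWAT and 40 between depots. Each was tested with limma 3.58.1's camera with a preset correlation of 0.01 and again with an estimated correlation, and with fry. With an estimated correlation no list was called in any comparison. Fry tests whether the genes of a list move on balance one way and compares them with no other genes. Named genes followed a rule fixed in advance: the 5 genes with the smallest p in each direction among those past the threshold with a mean of at least 5 CPM, up to 4 members of a list with the smallest p, and Lep, Agrp, Npy, Pomc and Cartpt in their tissues. Only part of the genes so named appear in the text, and some results are not reported here.

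Of 46078 gene identifiers 45229 (98.2%) were found in GENCODE M21 on GRCm38, which gave symbols, positions, GC content and transcript length; 849 had no symbol. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, are uncertain, since reads shared between copies could be lost or split.

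Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE factors, no filter on low counts, limma on log2(CPM + 1) of the deposited tables (computed from their counts), the last against the first 2 codes, the 48 pools as separate libraries with and without the pool number as a block or a sequencing run assumed from the index numbers of the libraries, 3 covariates for neighbouring brain tissue, a lymph node covariate, each diet or pool left out, and leaving out 4 series 1 diets whose adipose files carry another naming scheme. Chosen after seeing the data were offsets per library for GC content and transcript length (splines with 5 degrees of freedom), leaving out pool 1 of D14071613, the exchanged D14071618 and D14071620, and leaving out the 7 adipose libraries whose depot genes went against their label, the last also with DESeq2 or with muscle and epididymis covariates.

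The tests were first run on simulated data with the real means, dispersions and library sizes and genes of known change. This covered the fat-varied trend, series 2 minus series 1, the depot difference, the depot difference of the fat-varied trend, and any difference in the fat-varied series. The protein-varied trend, series 4 minus series 3 and the slope difference were not simulated. For the depot difference 81.6% of genes with a log2 change of 0.5 were recovered, and for series 2 minus series 1 82% in the hypothalamus, 2% in sWAT and 10% in eWAT. Under 0.1% of unchanged genes were called in the simulations without bias. In a further simulation each library was given the GC and length bias fitted to its real counts. In the fat-varied trend 570 unchanged genes (3.78%) were then called without the offsets and 0.0596% with them. The same splines made and removed this bias, so the simulation cannot show that the offsets remove bias of another form. The simulated spread was estimated without offsets and so already held this bias, which can lower the number of false calls. Other software was R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.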

Results

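The series measured RNA from male C57BL/6 mice kept for 12 weeks on 1 of 24 purified diets, coded D14071601 to D14071624, to ask how the fat and the protein of a diet relate to feeding and fat storage. The diets form 4 series of 6. In series 1 and 2 fat was fixed and protein varied, and in series 3 and 4 protein was fixed and fat varied. The labels give no nutrient level for a code and do not say which series had the higher fixed level, so a trend here runs along the order of the codes within a series and is not a dose. The hypothalamus, the brain region that sets hunger and body temperature, gave 48 libraries, 2 pools of 4 hypothalami for each diet. Subcutaneous white adipose tissue (sWAT) and epididymal white adipose tissue (eWAT, the fat pad beside the testis) gave 24 libraries each, 1 pool of 6 animals per diet and depot. A diet thus had no replicate there, and diets of a series stood in as the replicates.

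Reads assigned to genes numbered 20675321 to 42331050 per hypothalamus library (median 29291490), 29754277 to 43332251 in sWAT (median 36975024) and 27619739 to 45631291 in eWAT (median 35812554). In counts simulated on these libraries, the test recovered 80% of genes given a log2 trend of 0.5 in the hypothalamus, against 4% in sWAT and 2% in eWAT. In those fat pads it recovered 76% and 61.2% of genes given a trend of 2. Smaller diet effects in the fat pads were therefore mostly not detectable. Changes below are log2 values ± SE from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p. A trend is the fitted change from the first to the last code, averaged over both series of a pair.

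Along the codes of the fat-varied series, hypothalamic genes of protein synthesis and 2 hunger peptides fell in the main fit. As given below, none of them passed over all genes with offsets for GC content and transcript length, or without pool 1 of D14071613. In the main fit 27 of 28 measured ribosomal protein genes fell, and 28 with p adjusted over the list alone, among them Rpl10 (-0.36 ± 0.10, adjusted p = 0.0216) and Rps16 (-0.43 ± 0.13). Npy, the neuropeptide Y gene (GRCm38 chromosome 6, 49822710 to 49829507), fell by 0.80 ± 0.19 (adjusted p = 0.0196). Agrp, which encodes the agouti-related peptide made in the same arcuate neurons (chromosome 8, 105566698 to 105637393), fell by 0.86 ± 0.26 (adjusted p = 0.0244). In series 3 D14071613, the first code, stood apart, with Npy at 25.85 CPM against 12.47 to 15.71 in the other diets and Agrp at 5.678 against 2.447 to 3.326. In series 4 the first 2 codes were highest, with Npy at 19.49 and 17.21 CPM and Agrp at 3.997 and 3.971. Hcrtr2, an orexin receptor, rose by 0.50 ± 0.14 and Npy1r, a neuropeptide Y receptor, by 0.34 ± 0.10. In the list of 13 hunger peptides and receptors 3 genes rose and 4 fell (5 and 4 adjusted over the list alone), with an adjusted p of 0.93 for the list. Pomc (-0.27 ± 0.55, adjusted p = 0.718) and Cartpt (-0.24 ± 0.14, adjusted p = 0.195), which encode peptides that curb feeding, did not pass the test. The changes with the smallest p were in St8sia4, a sialyltransferase (ENSMUSG00000040710, chromosome 1, 95587682 to 95667571; 0.70 ± 0.13), Snx16, a sorting nexin (0.39 ± 0.07), and Chordc1, a chaperone partner (0.42 ± 0.08), which rose. Among those that fell they were in Laptm5, a lysosomal protein of microglia (-0.28 ± 0.05), Ephx1, an epoxide hydrolase (-0.38 ± 0.08), and Rela, an NF-kB subunit (-0.29 ± 0.06).

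In this trend 5005 of 15356 genes passed, 2496 higher and 2509 lower toward the last code, over the 12 diets of series 3 and 4. Of the 31 genes of mitochondrial respiration and the TCA cycle 9 fell (9 adjusted over the list alone), such as Ndufs3 of complex I (-0.34 ± 0.10) and Etfb, an electron carrier of fatty acid oxidation (-0.44 ± 0.13). The camera test called the ribosomal list (adjusted p = 4.83e-08) and the mitochondrial list (0.0337), and with an estimated correlation neither (adjusted p = 0.961 for both). The genes that rose had a median GC content of 43.2% and those that fell 55.2%, against 49.7% of all tested genes. With offsets for GC content and transcript length, 21 genes passed (19 higher, 2 lower) and no ribosomal gene did (3 adjusted over the list alone). Npy (-0.52, adjusted p = 0.0726) and Agrp (-0.52, adjusted p = 0.173) then missed the threshold. The edgeR count was 0 without pool 1 of D14071613 (2340 at an unadjusted p under 0.05), 0 without diet D14071613 (3025), D14071618 (5322), D14071620 (6084) or D14071624 (5410). It was 1752 without D14071617 and 7940 without D14071614, against 7266 at an unadjusted p under 0.05 and 5566 calls by DESeq2 with all diets. It was 0 from the second pools alone (675) and 6091 from the first. With D14071618 and D14071620 exchanged, as the deposited table names them, it was also 0 (5165), while the called genes kept 77.0% of their median change (0.31 to 0.24). Without pool 1 of D14071613 Npy had -0.50 (adjusted p = 0.296) and Agrp -0.39 (adjusted p = 0.427), and from the second pools alone Agrp turned in sign to 0.33.

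**Figure D1:**
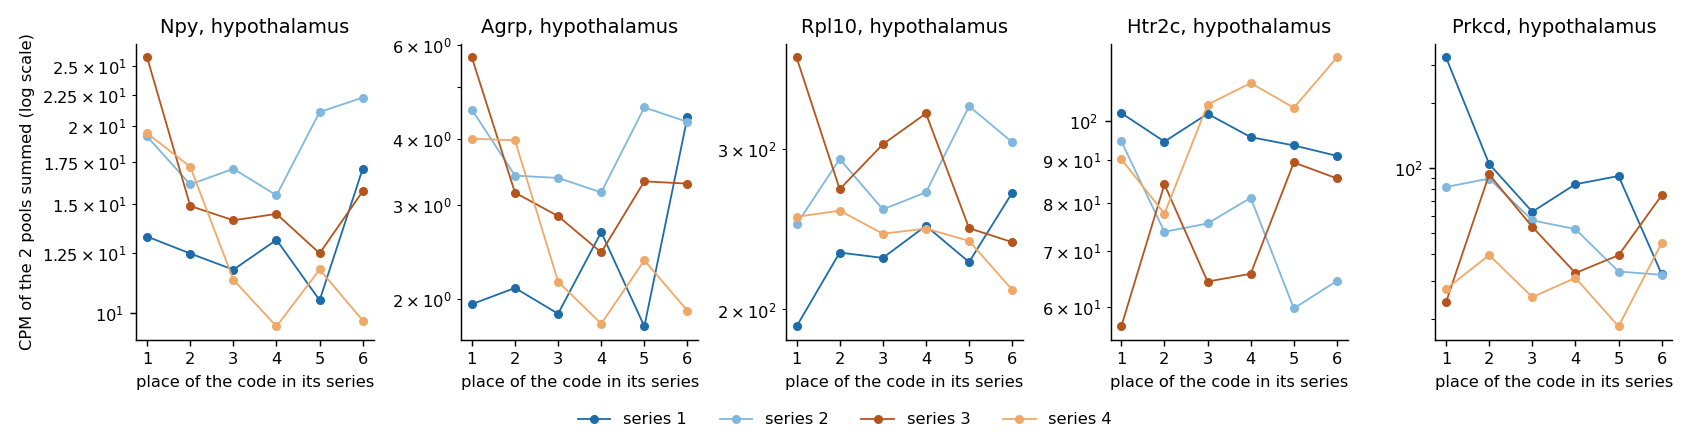
Expression of Npy, Agrp, Rpl10, Htr2c and Prkcd in the hypothalamus, in CPM (counts scaled to the reads assigned to genes) on the vertical axes, against the position of the diet code in its series, 1 to 6, with one colour for each of the 4 series. Each point is 1 diet with its 2 pools summed; Npy was highest in D14071613, the first code of series 3, at 25.8 CPM, and Prkcd in D14071601, the first code of series 1.

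**Figure D2:**
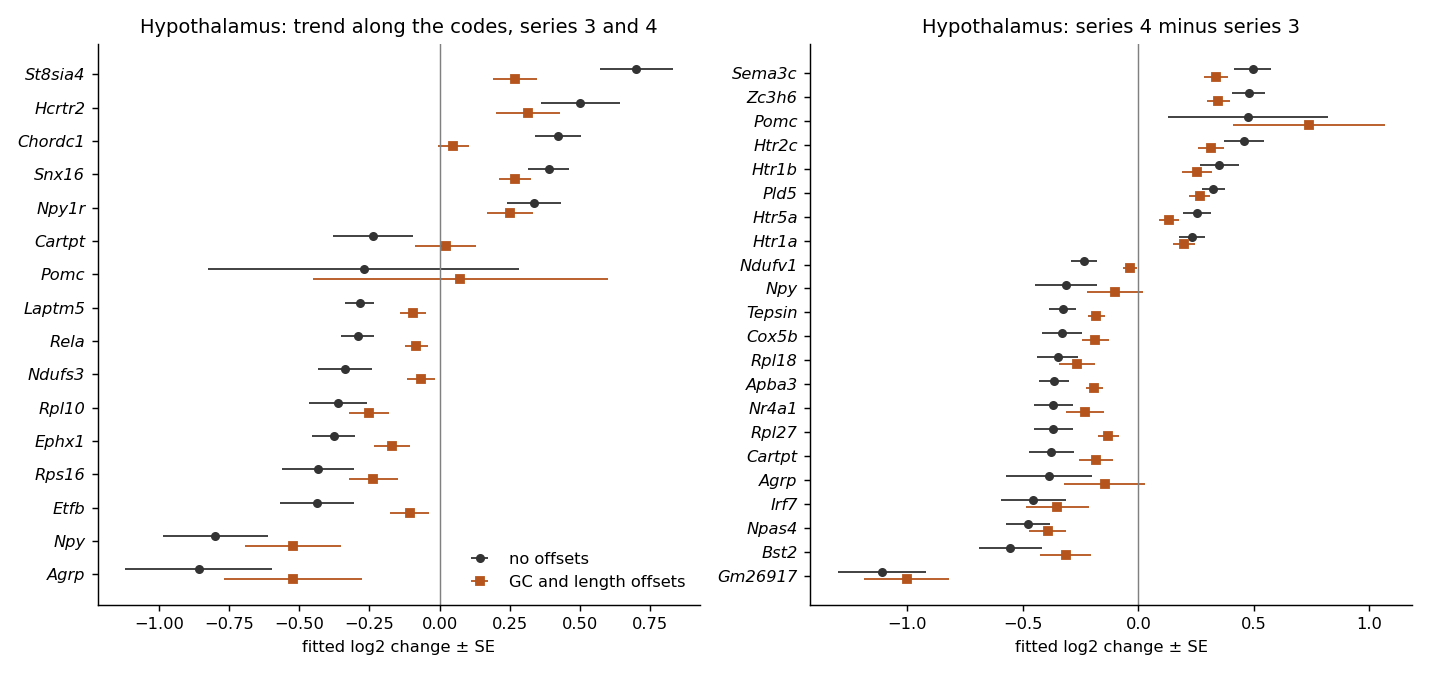
Fitted log2 changes of the named hypothalamic genes in the trend of the fat-varied series and in series 4 minus series 3, with and without offsets for GC content and transcript length. Points are estimates and bars are ± 1 SE; the trend of Npy was -0.80 without the offsets and -0.52 with them.

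Along the codes of the protein-varied series, markers of the thalamus, the brain region above the hypothalamus, fell in the hypothalamus libraries. All 9 measured thalamus genes fell, also when adjusted over the list alone, with a median of -1.15, among them Rora, a nuclear receptor (-1.15 ± 0.23, adjusted p = 0.0229), Prkcd, a kinase abundant in thalamic neurons (chromosome 14, 30595354 to 30626210; -2.07 ± 0.44), and Plekhg1 (-1.36 ± 0.26). Prkcd stood at 360 and 283 CPM in the pools of D14071601, the first code of series 1, against a median of 44.0 over the libraries. Of 20 genes of hypothalamic identity only Crhr2, a corticotropin releasing hormone receptor, rose (0.46 ± 0.09, adjusted p = 0.0233; 6 adjusted over the list alone, median 0.37). Avp, the vasopressin gene, rose by 1.27 ± 0.26 (adjusted p = 0.0229). Camera called both lists (adjusted p = 4.42e-08 and 3.06e-05), and with an estimated correlation neither (adjusted p = 0.469 for both). Fry, which tests whether the genes of a list move on balance one way, gave an adjusted p of 0.0179 for the thalamus list.

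Genes switched on by neuronal activity fell along the same codes. Of 17 immediate early genes 5 fell (7 adjusted over the list alone), among them Fosb (-0.68 ± 0.14), Fos (-0.58 ± 0.15, adjusted p = 0.0424), Fosl2 (-0.47 ± 0.12) and Dusp1 (-0.40 ± 0.10). Camera called this list (adjusted p = 0.00688; adjusted p = 0.469 with an estimated correlation). Of 18 circadian clock genes Hlf (-0.53 ± 0.12) and Nr1d1 (-0.26 ± 0.07) fell (5 lower and 1 higher adjusted over the list alone), and the list missed the threshold (adjusted p = 0.0593; adjusted p = 0.495 with an estimated correlation). With the GC and length offsets 7 immediate early genes and 5 clock genes fell, and both lists were then called (adjusted p = 4.58e-05 and 0.00196; adjusted p = 0.404 with an estimated correlation for both). Ribosomal protein genes had a median of 0.30, with 0 of 28 past the threshold over all genes by edgeR and 27 higher adjusted over the list alone (camera adjusted p = 9.19e-09; adjusted p = 0.469 with an estimated correlation). Agrp (0.48 ± 0.26, adjusted p = 0.214), Npy (0.22 ± 0.19, adjusted p = 0.416), Pomc (0.73 ± 0.53, adjusted p = 0.337) and Cartpt (0.35 ± 0.15, adjusted p = 0.133) did not pass the test. The smallest p values were those of Smoc1, a matrix protein that rose (ENSMUSG00000021136, chromosome 12, 81026808 to 81186414; 0.34 ± 0.05, adjusted p = 0.00820), with Mgp, the matrix Gla protein (0.89 ± 0.17), and Sfrp5, a Wnt inhibitor (0.45 ± 0.09). Among genes that fell they were those of Abhd12b (chromosome 12, 70154142 to 70183887; -2.60 ± 0.47, adjusted p = 0.0201), Fign (-0.83 ± 0.14) and Plekhd1 (-0.68 ± 0.12).

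In the protein-varied trend 422 genes passed, 104 higher and 318 lower, with 4550 at an unadjusted p under 0.05 and 1711 calls by DESeq2. With the offsets 776 passed, 98 higher and 678 lower. With 3 covariates for neighbouring brain tissue (thalamus, cortex and striatum markers) edgeR called 0 genes (527 at an unadjusted p under 0.05), and the medians of the ribosomal and the hypothalamic identity lists turned in sign to -0.092 and -0.035. The count was 0 without D14071601 (2129 unadjusted), D14071606 (2540) or D14071612 (4034), 2 without D14071611 and 30 without D14071607. It was 150 without D14071604, 818 without D14071602, 876 without D14071605 and 2018 without D14071608. Leaving out diets of the other pair, which set only the spread, gave 174 without D14071622, 184 without D14071624 and 188 without D14071623. It gave 267 without D14071619, 271 without D14071621, 672 without D14071613, 966 without D14071616 and 2399 without D14071614. The first pools alone gave 0 calls (1634 unadjusted) and the second pools 353.

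A test of any difference among the 6 diets of a series, which needs no order of the codes, used the 2 pools of each diet as replicates. In the fat-varied series it called 2 of 15678 genes, Ttr (adjusted p = 0.00238) and Chordc1 (adjusted p = 0.0265), with 3655 at an unadjusted p under 0.05 and 1930 calls by DESeq2. Without pool 1 of D14071613 it called 1911, and with the offsets 34. Ttr, the transthyretin gene made by the choroid plexus, stood at 714 CPM in pool 1 of D14071619 against a median of 3.07 over the libraries, and was singled out after its values were seen. In the protein-varied series 50 genes passed (1766 unadjusted, 647 by DESeq2, 224 with the offsets, 1730 without pool 1 of D14071613), and 149 with the pool number as a block.

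Between the protein-varied series, microglial, interferon response and ribosomal genes were higher in series 2 than in series 1, and serotonin receptor and thalamus genes lower. These results are from the fit without covariates for neighbouring brain tissue, with which 1 gene passed, as given below. All 28 ribosomal protein genes were higher, also when adjusted over the list alone (Rpl10 by 0.27 ± 0.07, Rps2 by 0.29 ± 0.07; camera adjusted p = 7.3e-10; adjusted p = 0.683 with an estimated correlation). Of 14 microglial genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with Aif1, the Iba1 gene, higher by 0.43 ± 0.09, the signalling adaptor Tyrobp by 0.35 ± 0.08 and the complement gene C1qc by 0.30 ± 0.07. Camera called the list (adjusted p = 0.017; adjusted p = 0.683 with an estimated correlation). Of 15 interferon response genes 6 were higher (7 adjusted over the list alone), such as Bst2 (0.54 ± 0.14) and Ifit3 (0.37 ± 0.08). Camera called this list (adjusted p = 0.0116; adjusted p = 0.693 with an estimated correlation). Of 11 genes of serotonin synthesis, transport and reception 4 were lower (5 adjusted over the list alone), with Htr2c, the receptor 2C gene (ENSMUSG00000041380, chromosome X, 146962513 to 147197277), lower by -0.40 ± 0.09 (adjusted p = 0.0121) and Htr7 by -0.20 ± 0.04. Camera called the serotonin list (adjusted p = 0.0259; adjusted p = 0.683 with an estimated correlation), and fry gave an adjusted p of 0.0217. Htr2c averaged 96.6 ± 4.66 CPM in series 1 and 74.9 ± 12.4 CPM in series 2 (SD, n = 6 diets each).

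Agrp (0.67 ± 0.19, adjusted p = 0.0218), Npy (0.48 ± 0.13, adjusted p = 0.0218), Hcrt, the orexin gene (0.56 ± 0.13), and Ghrh, the growth hormone releasing hormone gene (0.57 ± 0.14), were higher in series 2, while Pomc (0.53 ± 0.35, adjusted p = 0.246) and Cartpt (0.11 ± 0.10, adjusted p = 0.397) did not pass the test. Agrp averaged 2.46 ± 0.996 CPM in series 1 and 3.89 ± 0.643 CPM in series 2 (SD, n = 6 diets each). Markers of neighbouring tissue moved as well. All 9 thalamus genes were lower (9 adjusted over the list alone; Ntng1 -0.56 ± 0.12, Slitrk6 -0.68 ± 0.15), and 8 of 20 genes of hypothalamic identity were higher and 1 lower (10 and 1 adjusted over the list alone). Among neuronal genes 7 of 12 were lower (7 adjusted over the list alone), Slc17a6, a vesicular glutamate transporter, by -0.38 ± 0.08. Camera gave adjusted p = 0.000123, 0.000149 and 0.0213 for these lists, and adjusted p = 0.683 with an estimated correlation for each. The pituitary genes Gh (7.11 ± 1.29) and Cga were higher, 2 of 4 in that list (2 adjusted over the list alone; median 0.86, mean 2.22; camera adjusted p = 0.0539; adjusted p = 0.683 with an estimated correlation). Gh reached 24.3 CPM in pool 2 of D14071610 alone. The smallest p values belonged to Smoc1 (0.23 ± 0.03) and Fabp7, a fatty acid binding protein of glia (0.50 ± 0.08), which were higher. Among lower genes they belonged to Fgf12 (-0.36 ± 0.06) and Chrm2, a muscarinic acetylcholine receptor (chromosome 6, 36388084 to 36528414; -0.57 ± 0.10, adjusted p = 0.0101).

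Between series 2 and 1, 4078 genes passed, 1723 higher and 2355 lower in series 2 (6721 at an unadjusted p under 0.05, 4811 by DESeq2). With the GC and length offsets 1682 passed, 324 higher and 1358 lower, of which 3 ribosomal, 3 microglial, 2 interferon and 3 serotonin genes. Agrp (0.47, adjusted p = 0.0796) and Npy (0.30, adjusted p = 0.108) then missed the threshold. With the 3 covariates for neighbouring brain tissue 1 gene passed, Gm20604, named after its value was seen. The called genes kept 43.0% of their median change (0.23 to 0.098, median SE 0.068 to 0.078), and 52.3% with the offsets. A differing share of neighbouring tissue may thus account for most of it, and GC and length bias for much. The count was 413 without D14071611, 913 without D14071601, 937 without D14071608, 1497 without D14071605 and 2247 without D14071603, and from the second and the first pools alone 1911 and 0 (2443 unadjusted).

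Between the fat-varied series, serotonin receptor genes were higher in series 4 than in series 3, and ribosomal, mitochondrial, immediate early and interferon response genes were lower. The serotonin, ribosomal and interferon lists moved the opposite way in series 2 minus series 1. Genes higher in series 4 had a median GC content of 44.5% and lower ones 54.4%. The correlation over genes of a diet's log2 deviation with GC content averaged -0.21, 0.17, 0.09 and -0.27 in series 1 to 4 (SD 0.14, 0.29, 0.26 and 0.33). Of the 11 serotonin genes 7 were higher (7 adjusted over the list alone), among them Htr2c (0.46 ± 0.09, adjusted p = 0.00460), Htr1b (0.35 ± 0.09), Htr5a (0.25 ± 0.06) and Htr1a (0.23 ± 0.06). Camera called the list (adjusted p = 0.0165; adjusted p = 0.911 with an estimated correlation), and fry gave an adjusted p of 0.0149. With the GC and length offsets 7 serotonin genes were again higher and fry gave an adjusted p of 0.00954. Htr2c averaged 74.3 ± 13.6 CPM in series 3 and 101 ± 15.0 CPM in series 4 (SD, n = 6 diets each). Of 17 immediate early genes 8 were lower (9 adjusted over the list alone), such as Npas4 (-0.48 ± 0.10) and Nr4a1 (-0.37 ± 0.08), and 2 with the offsets. Camera called the list (adjusted p = 0.022; adjusted p = 0.911 with an estimated correlation). Of 15 interferon genes 7 were lower (7 adjusted over the list alone), Bst2 by -0.55 ± 0.14 and Irf7 by -0.46 ± 0.14, and 3 with the offsets. Camera called the list (adjusted p = 0.0438; adjusted p = 0.911 with an estimated correlation). All 28 ribosomal genes were lower (28 adjusted over the list alone), Rpl27 by -0.37 ± 0.08 and Rpl18 by -0.35 ± 0.09, and 8 with the offsets. Without them camera called the list (adjusted p = 3.11e-07; adjusted p = 0.911 with an estimated correlation). Of 31 mitochondrial genes 18 were lower and 1 higher (19 and 1 adjusted over the list alone), Ndufv1 of complex I by -0.23 ± 0.06 and Cox5b of complex IV by -0.33 ± 0.09, and 6 were lower with the offsets. Without them camera called this list too (adjusted p = 0.0073; adjusted p = 0.911 with an estimated correlation).

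Cartpt was lower in series 4 (-0.38 ± 0.10, adjusted p = 0.00670; -0.19, adjusted p = 0.0742 with the offsets), while Agrp (-0.39 ± 0.19, adjusted p = 0.0930), Npy (-0.31 ± 0.13, adjusted p = 0.0615) and Pomc (0.48 ± 0.35, adjusted p = 0.269) did not pass the test. The smallest p values were those of Zc3h6, a zinc finger gene (chromosome 2, 128967402 to 129018563; 0.48 ± 0.07), Pld5 (0.32 ± 0.05) and Sema3c, a semaphorin (0.49 ± 0.08), which were higher. Among lower genes they were those of Gm26917, a long noncoding RNA (-1.11 ± 0.19), Apba3 (-0.37 ± 0.06) and Tepsin (-0.33 ± 0.06). Between series 4 and 3, 6886 genes passed, 3345 higher and 3541 lower (8201 at an unadjusted p under 0.05, 7070 by DESeq2), and 3420 with the offsets, 1900 higher and 1520 lower. The count was 2153 without pool 1 of D14071613, 3895 without diet D14071613, 3716 from the first pools alone and 0 from the second pools alone (4330 at an unadjusted p under 0.05). The slopes along the codes did not differ detectably between series 4 and 3, with 0 genes by edgeR, 2381 at an unadjusted p under 0.05 and 129 by DESeq2.

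In the fat pads, the depot label and the marker genes of the depot disagreed for 7 libraries. The difference between subcutaneous and visceral patterning genes, the mean log2(CPM + 1) of Tbx15, Shox2, En1 and Hoxc10 minus that of Wt1, Tcf21, Upk3b and Gata4, lay between 3.17 and 4.34 in 21 libraries labelled sWAT and between -2.59 and -0.10 in 20 labelled eWAT. It was -2.73, -1.77 and -1.98 in the libraries labelled sWAT of D14071604, D14071605 and D14071606, and 2.91, 3.49, 3.62 and 4.03 in those labelled eWAT of D14071604, D14071605, D14071606 and D14071611. No label was changed. The number of genes called in each fat pad comparison is given as labelled and again without these 7 libraries (3 labelled sWAT and 4 labelled eWAT), while genes and lists are as labelled unless stated. Leaving them out was an alternative chosen after the data were seen, in which series 1 rests on its first 3 codes, so that its trend is imprecise.

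**Figure D3:**
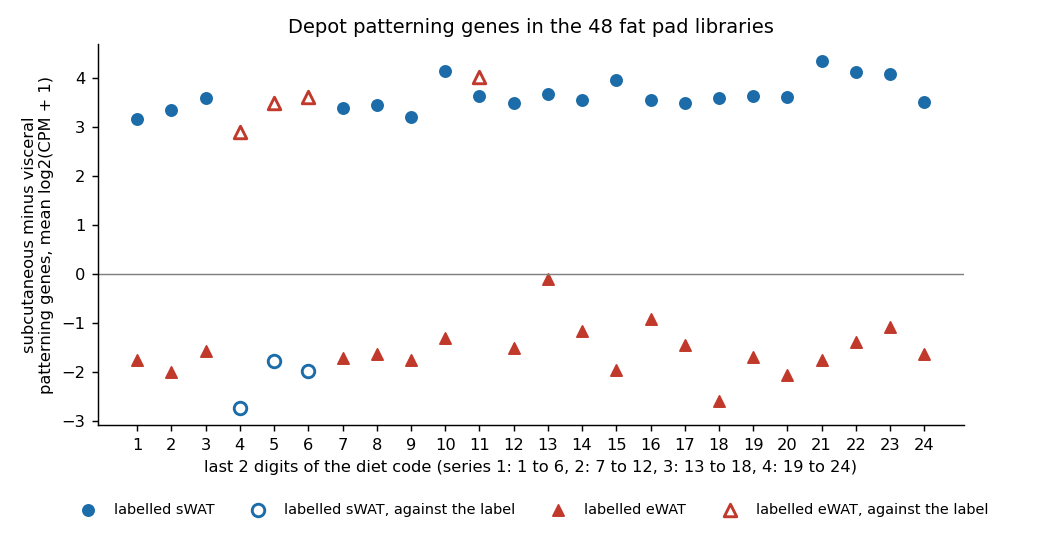
Mean log2(CPM + 1) of 4 subcutaneous minus 4 visceral patterning genes for each of the 48 adipose libraries against the diet code, with one colour per depot label. The libraries labelled sWAT of codes 04 to 06 lie below 0 with the eWAT libraries, and the libraries labelled eWAT of codes 04 to 06 and 11 lie at 2.91 to 4.03 with the sWAT libraries.

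Along the codes of the fat-varied series, Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), rose in sWAT by 3.58 ± 0.61. Pimreg, a mitotic gene, rose by 1.92 ± 0.32, while Gm14286, a noncoding RNA annotated as antisense, fell (adjusted p = 0.0496 each). Iqgap3, a scaffold gene of dividing cells, and Zim1, an imprinted zinc finger gene, also rose; both averaged under 5 CPM and were named after their values were seen. These 5 of 14524 genes passed, 4 higher and 1 lower (970 at an unadjusted p under 0.05, 87 by DESeq2), and 8 without the 7 libraries. Reads of Gm14286 cannot be told from those of the gene on the other strand. Of 18 cell cycle genes 0 passed over all genes by edgeR and 14 were higher adjusted over the list alone (17 without the 7 libraries), with a median of 1.58. Cdk1 had 1.54 ± 0.29 (adjusted p = 0.0699) and Tpx2 1.88 ± 0.48. Of 22 genes of de novo lipogenesis 0 passed over all genes and 7 were lower adjusted over the list alone, with Elovl6, a fatty acid elongase (chromosome 3, 129532355 to 129638495), at -2.75 ± 0.62 (adjusted p = 0.161), Acaca at -1.76 ± 0.49 and the desaturase Fads1 at -1.01 ± 0.26. The first code carried the trend of Elovl6, at 215.2 CPM in series 3 and 98.79 CPM in series 4, against 13.55 to 24.35 and 14.91 to 29.27 CPM at the others. Of 14 genes of lipid-associated macrophages 0 passed and 5 were higher adjusted over the list alone (0 without the 7 libraries), with Trem2 at 2.20 ± 0.80 (adjusted p = 0.508). Of 18 clock genes 0 passed and 6 were lower adjusted over the list alone, with Dbp and Nr1d1 both at -0.83 ± 0.25. Camera called these 4 lists (adjusted p = 3.94e-24, 3.48e-05, 1.69e-07 and 0.00131), and none with an estimated correlation (adjusted p = 0.315 for the cell cycle and 0.599 for the others). Lep, the leptin gene, had 1.01 ± 0.39 (adjusted p = 0.554).

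The sWAT fat trend count was 0 by edgeR without any 1 of 15 diets, D14071601, D14071602, D14071603, D14071605, D14071610, D14071611, D14071612, D14071613, D14071614, D14071617, D14071619, D14071620, D14071622, D14071623 and D14071624 (436 to 1084 genes at an unadjusted p under 0.05). It was 1 without D14071616, 3 without D14071615 or D14071621, 8 without D14071618, 22 without D14071604 and 23 without D14071609. Muscle genes varied among these pools, with Acta1, skeletal muscle actin, at 13440 CPM in the sWAT library of D14071622 and 12140 CPM in that of D14071621, and with a muscle covariate and without the 7 libraries, 8 genes passed. With a lymph node covariate 12 genes passed, and 9 without the 4 series 1 diets whose adipose files carry another naming.

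In eWAT the same trend gave 0 of 15125 genes by edgeR (1240 at an unadjusted p under 0.05, 51 by DESeq2). The values with the smallest p in the lists of fat synthesis, macrophages and matrix were those of Elovl6 (-2.34 ± 0.47, adjusted p = 0.584), Acly, ATP citrate lyase (-1.26 ± 0.34), Postn, a matrix protein (1.17 ± 0.33), Spp1, osteopontin (3.73 ± 1.57), and Gpnmb (3.70 ± 1.67). Of 22 lipogenesis genes 3 were lower adjusted over the list alone, with a median of -0.63 (camera adjusted p = 1.13e-05). The 14 lipid-associated macrophage genes (median 2.35) and the 22 matrix genes (median 1.05) held 0 calls, also adjusted over the list alone (camera adjusted p = 1.43e-10 for both). With an estimated correlation no list was called (adjusted p = 0.620 for these 3), and fry gave adjusted p = 0.507, 0.507 and 0.609 for them. Without the 7 libraries edgeR called 0 genes (1217 at an unadjusted p under 0.05) and DESeq2 84. Cyp1a1, which passed in sWAT, did not pass in eWAT. It went there from 0.99 to 14.7 CPM between the first and last code of series 3, and from 0.47 to 14.3 CPM in series 4. Elovl6 was highest at the first code, at 158.4 and 112.5 CPM in series 3 and 4, against 17.04 to 36.68 and 22.57 to 40.2 CPM at the others. Lep had 0.82 ± 0.66 (adjusted p = 0.684).

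**Figure D4:**
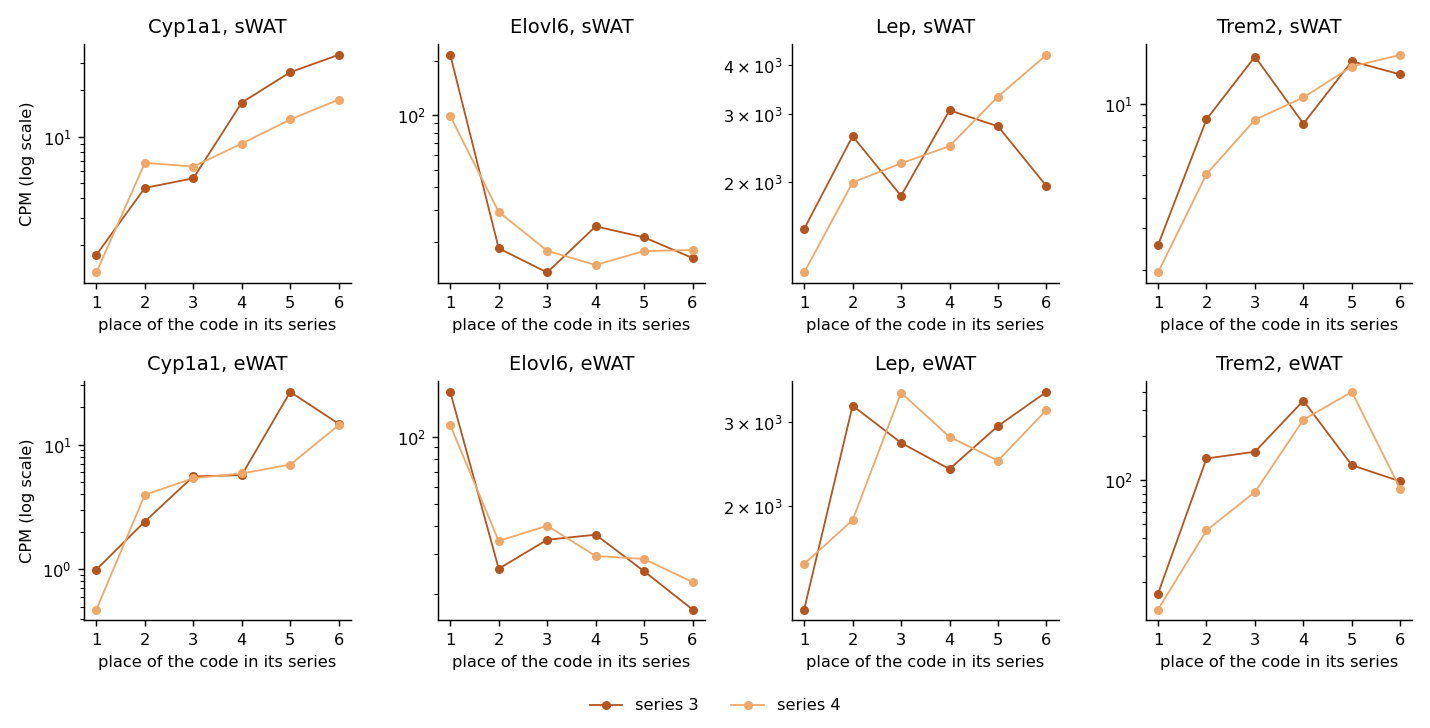
Expression in CPM of Cyp1a1, Elovl6, Lep and Trem2 in the libraries labelled sWAT and eWAT of the fat-varied series 3 and 4 against the position of the diet code, 1 to 6. Each point is 1 pool of 6 animals. Cyp1a1 passed the test in sWAT (3.58 ± 0.61 on the log2 scale) but not in eWAT. There it went from 0.99 to 14.7 CPM between the first and last code of series 3, and from 0.47 to 14.3 CPM in series 4. The other 3 genes passed in neither depot.

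Along the codes of the protein-varied series, macrophage genes rose and Schwann cell genes fell in the libraries labelled sWAT, with no calls by edgeR in these lists without the 7 libraries whose markers went against their label. As labelled, 195 genes passed, 178 higher and 17 lower (1579 at an unadjusted p under 0.05, 503 by DESeq2). Plau, the urokinase gene (chromosome 14, 20836660 to 20843385), rose by 1.73 ± 0.22 (adjusted p = 0.00340), Mgp by 1.72 ± 0.25 and Hexa, a lysosomal enzyme, by 1.01 ± 0.15, while Elovl3 (-5.26 ± 1.18) and Ntrk3 (-1.55 ± 0.36) fell. Of 16 macrophage genes 8 rose (15 adjusted over the list alone), such as C1qb (1.13 ± 0.19) and Adgre1, the F4/80 gene (1.99 ± 0.38). Of 14 lipid-associated macrophage genes 6 rose (12 adjusted over the list alone), such as Gpnmb (3.04 ± 0.63) and Lipa (1.41 ± 0.23). Of 12 Schwann cell genes 3 fell (7 adjusted over the list alone). Camera called the lists (adjusted p = 9.76e-21, 4.32e-18 and 5.89e-08), and none with an estimated correlation (adjusted p = 0.0911, 0.0911 and 0.240). Without the 7 libraries edgeR called 0 genes (2109 at an unadjusted p under 0.05; 97 by DESeq2), and 0 in each of these lists also when adjusted over the list alone. The Schwann cell list then had a median of -1.05, against -1.44 as labelled (camera adjusted p = 0.0737; adjusted p = 0.813 with an estimated correlation), and over the 195 genes 33.5% of the median change was left (1.10 to 0.37, median SE 0.23 to 0.43), so the lost calls do not show that these genes stayed level. The macrophage list had a median of 0.10 and a mean of -0.11 (adjusted p = 0.768; adjusted p = 0.957 with an estimated correlation). As labelled, the count was 0 without D14071607 (839 unadjusted), 51 without D14071601, 65 without D14071611 and 93 without D14071605, and 318 without the 4 diets of the other file naming. Lep had 1.03 ± 0.39 (adjusted p = 0.286).

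In eWAT the protein trend gave 0 genes by edgeR (1083 at an unadjusted p under 0.05, 177 by DESeq2), and Lep had 0.44 ± 0.75 (adjusted p = 0.945). The count was 685 without D14071612, 34 without D14071607 and 1 without D14071601. Without the 7 libraries 1 gene passed, Gm24270, a gene with no assigned function that was named after its value was seen (1164 at an unadjusted p under 0.05, 276 by DESeq2).

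Between the protein-varied series, macrophage and cell cycle genes were lower and mitochondrial genes higher in series 2 of sWAT as labelled, and 1 gene passed without the 7 libraries. As labelled 4013 genes passed, 1585 higher and 2428 lower (5853 at an unadjusted p under 0.05, 4749 by DESeq2). Markers of other tissue differed as well, with wide spread. The mean log2(CPM + 1) of the skeletal muscle genes was 2.87 ± 3.35 in series 1 and 5.21 ± 4.27 in series 2, and that of the lymph node genes 3.53 ± 2.04 and 4.93 ± 2.21 (SD, n = 6 diets each). Lipa, the lysosomal acid lipase gene (ENSMUSG00000024781, chromosome 19, 34492318 to 34527474), was lower by -1.72 ± 0.16 (adjusted p = 1.49e-05; -0.78, adjusted p = 0.211 without the 7 libraries), at 312 ± 230 CPM in series 1 and 71.5 ± 4.74 CPM in series 2 (SD, n = 6 diets each). Galc (-1.10 ± 0.10) and Mgp (-1.68 ± 0.17) were lower, and Slc25a38, a mitochondrial carrier (0.55 ± 0.07), and Tst (1.57 ± 0.22) were higher. All 14 lipid-associated macrophage genes were lower (14 adjusted over the list alone), with Gpnmb at -3.55 ± 0.43, and 15 of 16 macrophage genes (15 adjusted over the list alone), with Cd68 at -2.27 ± 0.26 and Adgre1 at -2.37 ± 0.26. Of 18 cell cycle genes 17 were lower (18 adjusted over the list alone), Cdk1 by -1.21 ± 0.19. Of 31 mitochondrial genes 24 were higher (28 adjusted over the list alone), Ndufv1 by 0.87 ± 0.17. Camera called these lists (adjusted p = 2.64e-13, 2.26e-13, 7.53e-10 and 4.14e-12), and none with an estimated correlation (adjusted p = 0.321, 0.350, 0.379 and 0.379).

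Without the 7 libraries none of the genes in these 4 lists passed by edgeR. Their medians were then -0.78, -0.40, -0.57 and -0.05, the last turned in sign, and camera called the first 3 (adjusted p = 0.00125, 0.00575 and 0.00211; adjusted p = 0.763 with an estimated correlation). The 1 gene that passed was Glyctk, glycerate kinase (-1.89 ± 0.25, adjusted p = 0.0272; -0.79 ± 0.21 as labelled), named after its values were seen, with 2356 genes at an unadjusted p under 0.05 and 415 by DESeq2. Lep, at 2466 ± 689 CPM in series 1 and 1301 ± 605 CPM in series 2 (SD, n = 6 diets each), was lower as labelled (-0.95 ± 0.26, adjusted p = 0.0117) and had -1.61 (adjusted p = 0.129) without them. As labelled, the count was 2529 without D14071607 and 2619 without D14071612, and 365 without the 4 diets of the other file naming, all in series 1.

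In eWAT as labelled, ribosomal and epididymis genes were higher and cell cycle genes lower in series 2 than in series 1. Of 28 ribosomal genes 18 were higher (24 adjusted over the list alone), such as Rpl13a (0.61 ± 0.15), and of 18 cell cycle genes 9 lower (15 adjusted over the list alone), such as Ccna2, a cyclin (-1.50 ± 0.37; camera adjusted p = 1.27e-08 and 1.5e-07; adjusted p = 0.782 with an estimated correlation for both). All 7 genes of the epididymis, the tissue beside this fat pad, were higher (7 adjusted over the list alone; median 9.66; camera adjusted p = 0.0138; adjusted p = 0.782 with an estimated correlation), and Gpx5 reached 20080 CPM in the eWAT library of D14071608. Nck1, an adaptor protein gene (chromosome 9, 100492293 to 100546134; -0.67 ± 0.09, adjusted p = 0.00770), and Peg3, an imprinted gene (-1.85 ± 0.31), were lower, and Cdk10 (0.38 ± 0.07) and Snrnp70, a splicing factor (0.52 ± 0.09), were higher. In all 3421 genes passed, 2184 higher and 1237 lower (5988 at an unadjusted p under 0.05, 4737 by DESeq2), and 0 by edgeR without the 7 libraries (1467 at an unadjusted p under 0.05, 4 by DESeq2). As labelled, the count was 32 without D14071612, 118 without D14071606, 761 without D14071601, 1015 without D14071607, 1785 without D14071608, 1791 without D14071604 and 2141 without D14071602. It was 0 by edgeR without the 4 diets of the other file naming, all in series 1 (1343 at an unadjusted p under 0.05). Lep, at 3016 ± 562 CPM in series 1 and 1313 ± 1008 CPM in series 2 (SD, n = 6 diets each), had -1.20 ± 0.43 (adjusted p = 0.0536).

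Between series 4 and 3 of the fat pads, 0 genes passed by edgeR in sWAT (552 at an unadjusted p under 0.05, 0 by DESeq2), while in eWAT edgeR gave 0 (411) and DESeq2 11. Leaving out the 7 libraries, edgeR gave 0 in sWAT (944) and 0 in eWAT (349), and DESeq2 0 and 6. The list with the smallest camera p in eWAT was that of 18 interferon response genes, with a median of -0.40 and 0 calls, also adjusted over the list alone (adjusted p = 5.59e-10; adjusted p = 0.915 with an estimated correlation); Isg15 had -0.59 ± 0.24. The slopes of series 4 and 3 gave 0 genes by edgeR in sWAT (280 unadjusted, 0 by DESeq2) and in eWAT (437 unadjusted, 0 by DESeq2). The slopes gave 0 by edgeR in both pads without the 7 libraries (573 unadjusted in each), with 2 by DESeq2 in sWAT and 1 in eWAT.

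Between the depots, with both libraries of a diet compared within the diet, mesothelial and macrophage genes were higher in eWAT and mitochondrial, brown adipocyte and Schwann cell genes higher in sWAT. Agt, the angiotensinogen gene (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), was higher in eWAT by 2.30 ± 0.37 (adjusted p = 0.00275), at 112 ± 68.1 CPM against 23.1 ± 21.2 CPM in sWAT (SD, n = 24 diets), and higher in eWAT in 20 of 24 diets. Penk, proenkephalin (2.63 ± 0.44), and Gpc3, a glypican (1.07 ± 0.17), were also higher in eWAT, and Shox2, a homeobox gene (chromosome 3, 66971727 to 66981771; -3.89 ± 0.66), Hoxc10 (-3.67 ± 0.64) and Slc7a6, an amino acid transporter (-0.49 ± 0.08), lower. Of 10 mesothelium genes 8 were higher (9 higher and 1 lower adjusted over the list alone), Upk3b by 6.34 ± 0.99 and Wt1 by 6.38 ± 1.06. Of 14 lipid-associated macrophage genes 9 were higher (12 adjusted over the list alone), Atp6v0d2 by 2.79 ± 0.58 and Trem2 by 2.42 ± 0.58. Of 16 macrophage genes 4 were higher (15 adjusted over the list alone), such as Cd68 (1.31 ± 0.43). Of 16 genes of endoplasmic reticulum stress 8 were higher (12 adjusted over the list alone), such as the chaperone gene Hspa5 (0.44 ± 0.12). The depot genes Shox2, Hoxc10, Wt1, Tcf21 and Upk3b were among those used to set libraries aside and are no independent evidence.

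Of 31 mitochondrial genes 17 were lower in eWAT (28 adjusted over the list alone), Ndufs1 by -0.49 ± 0.11, and of 13 brown and beige adipocyte genes 6 (8 adjusted over the list alone), Cidea by -1.89 ± 0.41, Cox8b by -1.84 ± 0.40 and Ppargc1a by -0.85 ± 0.17. Of 21 genes of fatty acid oxidation 11 were lower and 1 higher (16 and 2 adjusted over the list alone), Cpt2 by -0.53 ± 0.15. Of 12 Schwann cell genes 8 were lower (8 adjusted over the list alone), Sox10 by -2.47 ± 0.45. Of 18 clock genes 8 were lower and 1 higher (13 and 2 adjusted over the list alone), Dbp by -0.39 ± 0.11. Neighbouring tissue moved with the depot: 9 of 15 skeletal muscle genes were lower in eWAT (15 adjusted over the list alone; Myh4 -10.60 ± 2.12) and 8 of 9 epididymis genes higher (9 adjusted over the list alone; Adam7 9.60 ± 2.33). Camera called all 11 lists named for the depots, with the weakest for the epididymis (adjusted p = 0.000778), and none with an estimated correlation (adjusted p = 0.508 to 0.552).

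As labelled 2839 of 15952 genes differed between the depots, 1550 higher and 1289 lower in eWAT (5589 at an unadjusted p under 0.05, 4631 by DESeq2). Without the diets of the 7 libraries 6757 of 15650 differed, 3557 higher and 3200 lower. Of the lists, all 31 mitochondrial genes, 15 macrophage genes and 12 lipid-associated macrophage genes passed in the directions above, and 1 macrophage gene passed lower in eWAT. With muscle and epididymis covariates beside this, 1854 genes passed. Camera then still called the mitochondrial, brown adipocyte and fatty acid oxidation lists, with medians of -0.19, -0.47 and -0.26 (adjusted p = 6.21e-05, 0.0138 and 0.00921) and 4, 3 and 1 genes lower and 1 oxidation gene higher. It did not call those of endoplasmic reticulum stress and skeletal muscle (adjusted p = 0.0836 and 0.404). The covariates were the means of the muscle and epididymis lists, so the lost call of the muscle list says nothing about the depots. The epididymis list stayed called beside its own covariate (adjusted p = 0.0174). In this fit Ppargc1a, Cox8b, Cpt2, Hspa5 and Dbp missed the threshold. As labelled, the count was 4634 without D14071604, 1850 without D14071615 and 5084 without the 4 diets of the other file naming. Lep did not differ detectably between the depots (0.02 ± 0.17, adjusted p = 0.932), at 2160 ± 884 CPM in sWAT and 2385 ± 992 CPM in eWAT (SD, n = 24 diets). The trend of the fat-varied series did not differ detectably between the depots, with 0 genes by edgeR (141 at an unadjusted p under 0.05) and 0 by DESeq2 (291), and 0 by either without the 7 libraries (215 and 399), and Lep had a difference of -0.08 ± 0.68.

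**Figure D5:**
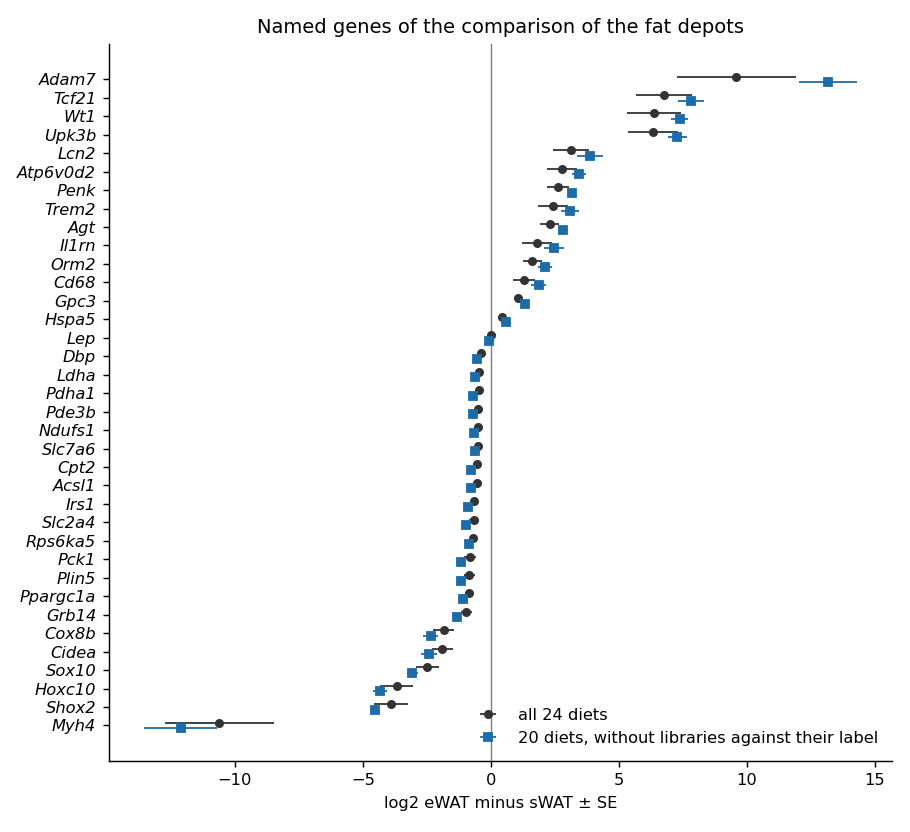
Log2 change, eWAT minus sWAT, of the named genes over all 24 diets and over the 20 diets whose libraries both matched their depot label. Points are edgeR estimates and bars are ± 1 SE; Agt was at 2.30 with 24 diets and 2.83 with 20.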

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

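In this part the bounds of the tests were set after the results were seen. The fits with covariates for neighbouring brain tissue and without D14071601 were planned, while the GC and length offsets, the library left out, the exchanged diets, the fits without 7 adipose libraries, the slopes on the depot difference and the orders compared below were chosen after the results were seen.

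In the hypothalamus 5005 genes were called along the codes of the fat-varied series and 6886 between series 4 and 3, and the genes that rose in the trend had a lower GC content than those that fell. With covariates for thalamus, cortex and striatum the trend's called genes kept 86.0% of their median change and 3128 stayed called. This argues against these as the whole cause, while choroid plexus and pituitary were not tested. For the series difference the offsets left 48.7% of the median change of its calls (0.22 to 0.11, median SE 0.062 to 0.044), and 2729 stayed called. GC and length bias may thus account for much of its size. The calls that stayed argue against the bias captured by the offsets as the whole cause, while bias that the offsets miss was not tested. For the trend the offsets left 43.8% of the median change (0.31 to 0.14, median SE 0.094 to 0.064) and 21 of the calls, so GC and length bias may account for most of its size. The calls ended because the changes shrank more than their error. In counts simulated with the fitted bias 570 unchanged genes were called. The simulated spread already held this bias, so that number may be too low and cannot be set against the 5005 genes called. Without a single library, pool 1 of D14071613, 54.2% of the median change was left (0.31 to 0.17, median SE 0.094 to 0.092). Its log2 deviations correlated with GC content at 0.53 over genes, against -0.14 in pool 2 of the same diet. The mean chi-square per gene between these pools was 147.8, against a median of 10.64 over diets. The deviation of pool 1 was thus not shared by the other pool of its diet, while the source of the change that was left stays open. Exchanged names of D14071618 and D14071620, as the deposited table has them, cannot be told apart from the diets as the source. With the names exchanged 77.0% of the median change was left (0.31 to 0.24, median SE 0.094 to 0.093). Both shares lay between the bounds, and the calls ended at 0 of 5005 in each because the change shrank while its error hardly did. The fat content of the diets stays open as a biological explanation and was not tested on its own, since the labels give no level for a code.

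Along the codes of the protein-varied series 422 hypothalamic genes were called, and all 9 thalamus genes, also measured in hypothalamus, fell, of which Prkcd stood at 360 and 283 CPM in the pools of D14071601. The tables argue against GC and length bias, as far as the offsets capture it, as the whole cause, since with the offsets the called genes kept 77.8% of their median change and 330 stayed called. With covariates for thalamus, cortex and striatum 36.3% of the median change was left (0.46 to 0.17, median SE 0.11 to 0.13) and 0 calls by edgeR (527 genes at an unadjusted p under 0.05). The change shrank while its error grew, so a changing share of neighbouring tissue in the dissected pieces may account for most of it. Without D14071601 the called genes kept 82.6% of their median change, also with 0 calls (2129 at an unadjusted p under 0.05), and the protein content of the diets stays open and untested.

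In the fat pads 4013 genes in sWAT and 3421 in eWAT were called between series 2 and 1, where 3 libraries labelled sWAT and 3 labelled eWAT of series 1, and 1 labelled eWAT of series 2, had depot genes against their label. Over 14223 genes the sWAT difference had a slope of -0.515 on the eWAT minus sWAT difference of series 3 and 4. These share no library with it. The slope was -0.896 to -0.233 with 1 diet left out and 0.421 without the 7 libraries. Only with them was it in the range set for 3 of 6 libraries of the other depot. As they were picked by depot genes, this cannot show they made many calls. In eWAT the slope was 0.491 (0.273 to 0.622 with 1 diet left out) and 0.323 without the 7 libraries, both inside the range set. Their contribution stays open, as does that of epididymis, whose genes were higher in series 2. The diets cannot be told apart from these, since without the 7 libraries only 3 diets of series 1 stay. The called genes then kept 43.2% of their median change in sWAT (0.61 to 0.27, median SE 0.16 to 0.28). In eWAT they kept 101% (0.80 to 0.82, median SE 0.23 to 0.51). In D14071604 to D14071606 both depots were out of place, as an exchange of tubes or names would need, while in D14071611 only eWAT was.

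A diet was marked where its gap to the nearest diet, as a share of the series' range, passed Dixon's 95% limit. This held in 24 of 116 groups. Measures overlap and Ttr was chosen after it was seen, so no chance rate is given. In the hypothalamus the mean of the cortex genes was highest in D14071612 (4.82 against 4.18 in the nearest diet, share 0.807) and D14071624 (4.13 against 3.98, share 0.687). That of the striatum genes was highest in D14071601 (5.36 against 4.96, share 0.808) and lowest in D14071611 (4.82 against 4.89, share 0.734), all as mean log2(CPM + 1). The mean of the choroid plexus genes was highest in D14071601 (2.70 against 2.18, share 0.699) and D14071619 (3.38 against 2.00, share 0.934). Ttr stood at 111 CPM in D14071601 against 17.5 (share 0.856), and at 27.0 in D14071612 against 8.00 (share 0.740). It stood at 13.0 in D14071614 against 5.04 (share 0.704) and at 365 in D14071619 against 2.75 (share 0.997). The correlation over genes of the log2 deviation with GC content was lowest in D14071607 (-0.384 against 0.160, share 0.631).

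Agrp was highest in D14071606 (4.39 CPM against 2.67, share 0.658) and in D14071613 (5.68 against 3.33, share 0.728), where Npy (25.8 against 15.7, share 0.758) and Pomc (100 against 60.4, share 0.732) were also highest. Pomc was highest in D14071622 as well (236 CPM against 60.7, share 0.873), and Cartpt was lowest in D14071601 (63.8 CPM against 87.9, share 0.868). In the libraries labelled sWAT the mean of the muscle genes was highest in D14071603 (9.69 against 1.84, share 0.931), the depot gene difference in D14071615 (3.97 against 3.67, share 0.629) and Cyp1a1 in D14071607 (32.0 CPM against 13.8, share 0.643). In those labelled eWAT the B cell and lymph node genes were highest in D14071602 (nearest diet 2.08, share 0.770). The muscle genes were highest in D14071604 (8.34 against 2.22, share 0.881) and D14071611 (7.52 against 2.35, share 0.822), and the depot gene difference in D14071611 (4.03 against -1.31, share 0.924).

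Other splits of the same diets into groups of the same sizes, or other orders of the codes within a series, were drawn 50 times per tissue and 30 times for the depots, the real one included. In the hypothalamus 1 of 50 gave as many calls as the real one for series 2 minus series 1 (4078, highest other 0), for series 4 minus series 3 (6886, highest other 0) and for the protein trend (422, highest other 0). Chance was excluded at 5% for these, with no correction for the number of comparisons. For the fat trend it was 2 of 50 (5005, highest other 6384). As another order gave more calls there than the real one, chance is not taken as excluded for the fat trend. With the GC and length offsets it was 1 of 50 for the protein trend (776, highest other 1) and 2 of 50 for the fat trend (21, highest other 2373). The order that gave most calls for the fat trend correlated at 0.543 with the real one, with and without the offsets, so whether its calls reflect the real order or another structure of the samples stays open. In sWAT it was 1 of 50 for series 2 minus series 1 (4013, highest other 981) and for the fat trend (5, highest other 0). It was 6 of 50 for the protein trend (195, highest other 3713), where chance was not excluded, and the order with most calls correlated at -0.229 with the real one, so that calls so many times the real count point to a structure of the samples. In eWAT it was 1 of 50 for series 2 minus series 1 (3421, highest other 3194). Where edgeR called 0 genes every split gives as many, 50 of 50, so the count of splits says nothing about chance. This was so for series 4 minus series 3 in sWAT (552 at an unadjusted p under 0.05, 0 by DESeq2, highest other 0) and in eWAT (411, 11 by DESeq2, highest other 0), and for the fat trend in eWAT (1240, 51 by DESeq2, highest other 0). It was also so for the protein trend in eWAT (1083, 177 by DESeq2, highest other 4184), where the order with most calls had a correlation of 0 with the real one, which again points to a structure of the samples. It was so as well for the slope difference of series 4 and 3 in sWAT (280, 0 by DESeq2, highest other 0), in eWAT (437, 0 by DESeq2, highest other 1) and in the hypothalamus (2381, 129 by DESeq2, highest other 3407). In the last the order with most calls correlated at -0.114 with the real one, which also points to such a structure. Between the depots 1 of 30 gave as many (2839, highest other 0).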

How the results depend on the processing

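The fits chosen after seeing the data were the GC and length offsets, alone or with the covariates for neighbouring brain tissue, and fits without pool 1 of D14071613, with D14071618 and D14071620 exchanged, or without the 7 adipose libraries against their depot label, alone, with DESeq2 or with covariates. The others were planned. Where no cause is named, the cause was not tested. Fits without diets or libraries rest on fewer samples, and small changes in the fat pads were mostly not recovered in the simulations. RLE factors left 179 gene results and 61 list results on the same side of the threshold, and changed 1 count by over 1.5 times.

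In the hypothalamus fat trend (5005 calls) limma on the deposited table, which names D14071618 and D14071620 the other way round, gave 0 (5287 genes at an unadjusted p under 0.05; method and naming changed together), the last against the first 2 codes 2093, and the covariates for neighbouring tissue 3192. The offsets gave 21, both together 50, the fit without pool 1 of D14071613 0 (2340 unadjusted) and the exchanged diets 0 (5165 unadjusted). In the protein trend (422) DESeq2 gave 1711, RLE factors 752, no filter 656, limma 244, and the last against the first 2 codes 0 (3403 unadjusted). The assumed run gave 1212, the covariates 0 (527 unadjusted), the offsets 776, both together 0 (776 unadjusted) and the fit without pool 1 of D14071613 639. For series 2 minus series 1 (4078) the assumed run gave 1883, the covariates 1, the offsets 1682 and both 1. For series 4 minus series 3 (6886) the offsets gave 3420, both 3630 and the fit without pool 1 of D14071613 2153. For the slope difference (0) DESeq2 gave 129, the assumed run 15 and both corrections 319. The test of any difference gave, in the fat-varied series (2), 1930 by DESeq2, 4578 with no filter, 1 with the covariates, 34 with the offsets and 1911 without pool 1 of D14071613. In the protein-varied series (50) these were 647, 2866, 0 (537 unadjusted), 224 and 1730.

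The pool number pairs no samples. With the 48 pools as separate libraries the replicate block gave 5547 calls in the fat trend, 1014 in the protein trend, 5 in the slope difference, 4645 and 7407 in the series differences. The values were 5568, 991, 0, 4699 and 7391 without the block, and with it 149 for any difference in the protein-varied series.

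In sWAT, series 2 minus series 1 (4013) gave 365 without the diets of the other file naming, 1 without the 7 libraries, 0 with the muscle covariate and 415 with DESeq2 on those. The fat trend (5) gave 87 by DESeq2, 0 with no filter (1294 unadjusted), 10 by limma and 0 for the last against the first 2 codes (929 unadjusted). It gave 9 without the other naming, 12 with the lymph node covariate, and 8, 8 and 306 without the 7 libraries, plain, with the muscle covariate and by DESeq2. The protein trend (195) gave 503, 64, 117 and 11 in the first 4 of these fits, 318 without the other naming, 374 with the lymph node covariate, and 0, 0 and 97 without the 7 libraries. The slope difference (0) gave 2 by DESeq2 without them. In eWAT, series 2 minus series 1 (3421) gave 1632 by limma, 0 without the other naming, and 0, 0 and 4 without the 7 libraries, plain, with the epididymis covariate and by DESeq2. By DESeq2 series 4 minus series 3 (0) gave 11 and, without the 7 libraries, 6, the slope difference (0) 1 without them and the fat trend (0) 51 and 84. The protein trend gave 177 by DESeq2 and 1, 43 and 276 without the 7. The depot count (2839) was 4631 by DESeq2, 5084 without the other naming, 6757 without the 7, 1854 with covariates and 7597 by DESeq2.

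Leaving out 1 diet or 1 set of pools gave 0 to 7940 calls in the hypothalamus fat trend, 0 to 2399 in the protein trend, 0 to 1 in the slope difference, 0 to 5791 for series 2 minus series 1 and 0 to 8700 for series 4 minus series 3. In sWAT it gave 0 to 23 in the fat trend, 0 to 264 in the protein trend and 2529 to 4910 for series 2 minus series 1. In eWAT it gave 0 to 685 in the protein trend and 32 to 4979 for series 2 minus series 1, and for the depots 1850 to 4634.

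Some values turned in sign. With the offsets, the offsets and covariates, and without pool 1 of D14071613, the fat trend of Pomc was 0.073, 0.17 and 0.17 and that of Cartpt 0.022, 0.079 and 0.036. The protein trend of Npy was -0.10 with the covariates and -0.083 with both. That of the ribosomal list was -0.092 and -0.078, and that of the hypothalamic identity list -0.035 with the covariates. For series 2 minus series 1 Cartpt was -0.073, -0.059 and -0.14 with the covariates, the offsets and both, and the thalamus list -0.045 with both. In the depot difference Lep was -0.083 without the other naming, -0.018 with the lymph node covariate, and -0.059 and -0.069 without the 7 libraries by edgeR and DESeq2. The lymph node list was 0.25 with its own covariate, and Ldha 0.10 with the muscle and epididymis covariates. Without the 7 libraries the eWAT protein trend of Lep was -0.18, -0.38 with the epididymis covariate and -0.19 by DESeq2. Without them the sWAT mitochondrial list for series 2 minus series 1 was -0.045, -0.087 with the muscle covariate and -0.058 by DESeq2. Lep in sWAT series 4 minus series 3 was -0.014 with the muscle covariate, and the epididymis list in eWAT was -0.64 with its own covariate. With 1 diet or set of pools left out, the fat trend ran from -0.68 to 0.42 for Pomc, -1.87 to 0.33 for Agrp and -0.56 to 0.15 for Cartpt. The protein trend ran from -0.036 to 0.38 for Npy and series 4 minus series 3 from -0.25 to 0.80 for Pomc. Lep ran from -0.32 to 1.42 in the eWAT protein trend, -0.20 to 0.18 in eWAT series 4 minus series 3, -0.030 to 0.11 between depots and -0.29 to 0.038 in the depot difference of the fat trend.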

Other observations

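The lists and genes below were fixed before the data were examined. Which of them to describe, as well as the single series and libraries, was chosen after the results were seen. Between the depots, some genes of fat and glucose handling were lower in eWAT than in sWAT, and some of inflammation higher. The 15 skeletal muscle genes were lower in eWAT as well (9 passed, median -4.72) and 4 of 16 macrophage genes higher, so the cells in which the changes arose are not known. Of 14 lipolysis genes 5 were lower (9 adjusted over the list alone), the phosphodiesterase Pde3b by -0.48 ± 0.14. Of 15 genes of fatty acid uptake and binding 4 were lower (5 adjusted over the list alone), Plin5 of the lipid droplet by -0.83 ± 0.21 and Acsl1 by -0.56 ± 0.14. Of 16 genes of adipocyte identity 5 were lower (5 adjusted over the list alone), Slc2a4, the insulin-regulated glucose transporter, by -0.65 ± 0.20 and Pck1 by -0.81 ± 0.25. Of 19 genes of glycolysis and glucose uptake 6 were lower (8 adjusted over the list alone), Pdha1 by -0.47 ± 0.12 and Ldha by -0.46 ± 0.14. Of 15 genes of insulin signalling 8 were lower (9 adjusted over the list alone), Irs1, the insulin receptor substrate, by -0.64 ± 0.14 and Grb14 by -0.95 ± 0.23. Of 16 genes of adipose inflammation 5 were higher (6 higher and 1 lower adjusted over the list alone), Lcn2, lipocalin 2, by 3.13 ± 0.69 and Il1rn by 1.80 ± 0.58. Camera called these 6 lists (adjusted p = 0.000658, 0.00336, 0.000309, 0.000385, 0.000591 and 0.00452), and none with an estimated correlation (adjusted p = 0.552 for each). Without the diets of the 7 libraries 10, 9, 12, 11, 10 and 11 genes of these lists passed in the same directions, with 1 inflammation gene lower. With muscle and epididymis covariates camera no longer called the lists of lipolysis, fatty acid uptake, adipocyte identity and glycolysis (adjusted p = 0.156, 0.414, 0.185 and 0.589), Slc2a4 and Pck1 missed the threshold, and Ldha had 0.10.

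In the hypothalamus, the 16 genes of the striatum, a region in front of the hypothalamus, held 2 that fell along the protein-varied codes, Scn4b (-0.87 ± 0.17, adjusted p = 0.0201) and Foxp1 (-0.36 ± 0.09), with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00688; adjusted p = 0.469 with an estimated correlation). Of the same genes 6 were lower in series 2 than in series 1 (6 adjusted over the list alone; camera adjusted p = 0.0322; adjusted p = 0.693 with an estimated correlation). Of 11 genes of ependymal cells and tanycytes, which line the third ventricle, 4 were higher in series 2 (6 higher and 1 lower adjusted over the list alone), Ccdc153 by 0.42 ± 0.10 and Rarres2 by 0.34 ± 0.08. Camera called the list (adjusted p = 0.0170; adjusted p = 0.683 with an estimated correlation). The 10 cortex and hippocampus genes held 0 calls by edgeR along the protein-varied codes (2 higher adjusted over the list alone; camera adjusted p = 0.691). In the fat pads the 16 lymph node genes held 0 calls between the depots, also adjusted over the list alone (median -1.04, camera adjusted p = 0.00116; adjusted p = 0.585 with an estimated correlation). They held 0 by edgeR between series 4 and 3 of sWAT, with 15 lower adjusted over the list alone (median -3.17, camera adjusted p = 0.00393; adjusted p = 0.941 with an estimated correlation).

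Within single series of the hypothalamus edgeR called 94 genes along the codes of series 1 and 1195 along those of series 4, and 0 in series 2 and in series 3. Single libraries stood apart in markers of other tissue. Slc17a7, a cortical glutamate transporter, reached 215 CPM in pool 1 of D14071612 against a median of 23.2, and Pomc 388 CPM in pool 1 of D14071622 against a median of 46.4. The sperm and epididymis genes Prm1 and Crisp1 stood at 560 and 3222 CPM in the library labelled sWAT of D14071604. Crisp1 stood at 4897, 4526 and 4201 CPM in the eWAT libraries of D14071612, D14071608 and D14071607, and Prm1 at 1067 CPM in that of D14071620. Cd79a of B cells reached 631 CPM in the sWAT library of D14071609.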
